A study of Homo sapiens with 14 samples.

How the data were processed

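The deposited files held FPKM values per gene, computed by the authors from reads that, per the submitters' processing notes, were checked with FastQC, trimmed with cutadapt and aligned with TopHat2 to the hg19 build, with no versions stated. The program that computed FPKM and its annotation are not given in the sources used here. Per the labels, mRNA was isolated from total RNA as poly(A) RNA and libraries were made with a Rubicon ThruPLEX kit. The strand of the reads is not stated there, so antisense, overlapping and near-identical genes are uncertain.

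The replicate 1 table had 28502 rows and 10 libraries, and the replicate 2 table had 25209 rows and 4 libraries. They shared 22919 symbols, with 5582 only in the first and 2290 only in the second. A row named unknown, 1 in all, was left out, and 0 columns were left unused. Absolute depth is unknown because FPKM values hold no counts. Relative depth was taken from ratios of low FPKM values between libraries of the same table.

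The tables were separate and held different rows, so every fold change was taken within a table. Values were log2(FPKM + 1), so fold changes of low genes are understated. Genes with a mean of at least 1 FPKM over the 8 libraries of DMSO, 2-PCPA, GSK343 and rapamycin were tested, which left 12603. All 4 groups entered 1 limma fit with the replicate number as a block, eBayes with an intensity trend, 3 residual and 5.42 prior degrees of freedom, and Benjamini-Hochberg adjustment at 0.05. The block was checked by correlating deviations from group means between libraries with the same number, which gave 0.710 to 0.784 over 6 pairs. Of the tested genes, 376 were listed at 0 in all 4 of these libraries of the replicate 1 table, and 362 were small RNA or clone rows. The median SE of a log2 fold change was 0.25 and its confidence interval reached 0.57 to either side at the median.

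Gene lists numbered 31, of which 29 had at least 5 tested members; lists were tested with camera of limma at a preset correlation of 0.01. Alternatives used a correlation estimated from the data and the rotation test fry of limma, whose p asks whether the members of a list change on average and not whether they change more than other genes. For the 6 compounds with 1 library, genes with a mean of at least 1 FPKM over the replicate 1 table were used (12804), and each list median was placed among 10000 random lists matched in 20 expression bins.

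These choices, the lists and 14 genes to be given in every comparison were made before the data were examined. Beyond those, genes were named by a fixed rule: the called genes, or, with fewer than 5 called, up to 8 per direction by size among those moving the same way in both replicates, up to 4 members of each called list, and 6 per direction for a single library. A few genes picked by this rule are not reported here. Some list members picked by it were left out of the prose for length, above all from the longer or less shifted lists (ribosomal proteins, ribosome biogenesis, histone genes, interferon response, respiratory chain, heat shock, glycolysis and NF-kB). For single libraries, small RNA and clone rows were passed over, 4 to 6 per direction, a choice made after the values were seen. The pattern for such rows was widened to symbols with a _ or / character after the rankings of single libraries were seen. Leaving them out of the fit, as well as leaving out rows listed at 0 throughout the replicate 1 table, was an alternative chosen after the data were seen. Quantile normalization and TPM scaling of gene lists were not planned either. The same holds for leaving out 2-PCPA replicate 1 in comparisons without 2-PCPA.

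The alternatives were pseudocounts of 0.1 and 5, no filter on low values, a mean of at least 5 FPKM, median centring, quantile normalization, TPM scaling, no replicate block, limma without the trend, robust eBayes, only the 2 groups compared, and each library left out. A 1-library group in those fits was assumed to vary like the others. Small RNA and clone rows lower the prior degrees of freedom, which rose from 5.42 to 24.8 without them and to 12.8 without rows listed at 0 throughout the replicate 1 table.

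In a self-test, 20 simulated data sets of 12603 genes with 200 changed genes each were run through the same fit. It recovered 30.9% of genes changed by 1 log2, 95.6% changed by 2 and 98.6% changed by 3. There were 15.45 false calls per simulation, and 1.6 in an unchanged comparison. With at most 200 changed genes to recover, 15.45 false calls were a larger share of the calls than the adjustment threshold allows. The adjusted p-values were thus too small in the simulations. Calls just past the threshold in the data may likewise be false more often than their adjusted p states. The autophagy core list shifted by 0.3 was called in 20 of 20 simulations at the preset correlation and in 0 of 20 with the estimated correlation, so the loss of list calls with the estimated correlation does not separate a true shift of this size from none. Simulated genes varied independently of each other. The 20 of 20 therefore cannot show whether the preset correlation calls too many lists when their genes vary together. Of 200 random lists 1 lay above the 99th and 2 below the 1st percentile, and all 200 lay above the 99th after a shift of 1 log2.

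Gene names and neighbours for the listed-at-0 check came from a GRCh38 reference, another assembly than that of the files. Genes were placed in a region by their start positions in that reference. The work used R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.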

Results

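RNA was sequenced from U2OS cells, an established human osteosarcoma line, after treatment with 9 small molecules or with the solvent DMSO at 0.5% by volume. The panel covered histone-modifying and histone-binding proteins together with rapamycin, an inhibitor of the growth kinase mTOR that is widely used to induce autophagy. The compounds were 2-PCPA (tranylcypromine, an inhibitor of the H3K4 demethylase KDM1A and of monoamine oxidases; 1 mM, 12 h), GSK343 (an EZH2 inhibitor; 10 μM, 24 h), rapamycin (5 μM, 24 h), SAHA (1 μM, 24 h) and VPA (20 μM, 24 h), both histone deacetylase inhibitors, GSK-J4 (a KDM6 inhibitor; 20 μM, 12 h), BIX-01294 (5 μM, 12 h) and BRD4770 (20 μM, 24 h), both directed at the EHMT methyltransferases, and UNC1215 (an L3MBTL3 ligand; 50 μM, 24 h). The series title names H3K4 demethylation and autophagy, so the central questions were what 2-PCPA changed and how this compared with rapamycin.

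There were 14 libraries. DMSO, 2-PCPA, GSK343 and rapamycin had 2 replicates each, and the other 6 compounds had 1 library each. Replicate 1 of all 10 groups was in one FPKM table and replicate 2 of 4 groups in another. The tables were separate and held different rows, so levels were compared only within a table and are given per replicate. Libraries of the replicated groups correlated at 0.944 to 0.960 within the replicate 1 table and at 0.929 to 0.940 within the replicate 2 table. Across tables they correlated at 0.789 to 0.811, replicates of the same group included. What set the tables apart was not tested. The files held no counts and the depth of the libraries is unknown. The steps between low FPKM values gave depth relative to DMSO of the same table, from 0.551 (BIX-01294) to 1.23 (SAHA) in the replicate 1 table and from 0.688 (GSK343) to 0.818 (2-PCPA) in the replicate 2 table. Between 12045 and 13157 genes had at least 1 FPKM in a library. The 2-PCPA replicate 1 library stood apart from its table. Its median log2 fold change against DMSO over 12603 tested genes was −0.42, where replicate 2 gave 0.01. It had FPKM above 0 for 28.5% of 393 olfactory receptor genes, which are normally silent outside sensory tissue, where the other 9 libraries had 2.80% to 6.62%. The medians of gene lists are therefore given relative to the median of all genes, which was −0.20 for 2-PCPA over both replicates. Values of single genes are against DMSO and include that shift. The labels do not say that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

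**Figure D1:**
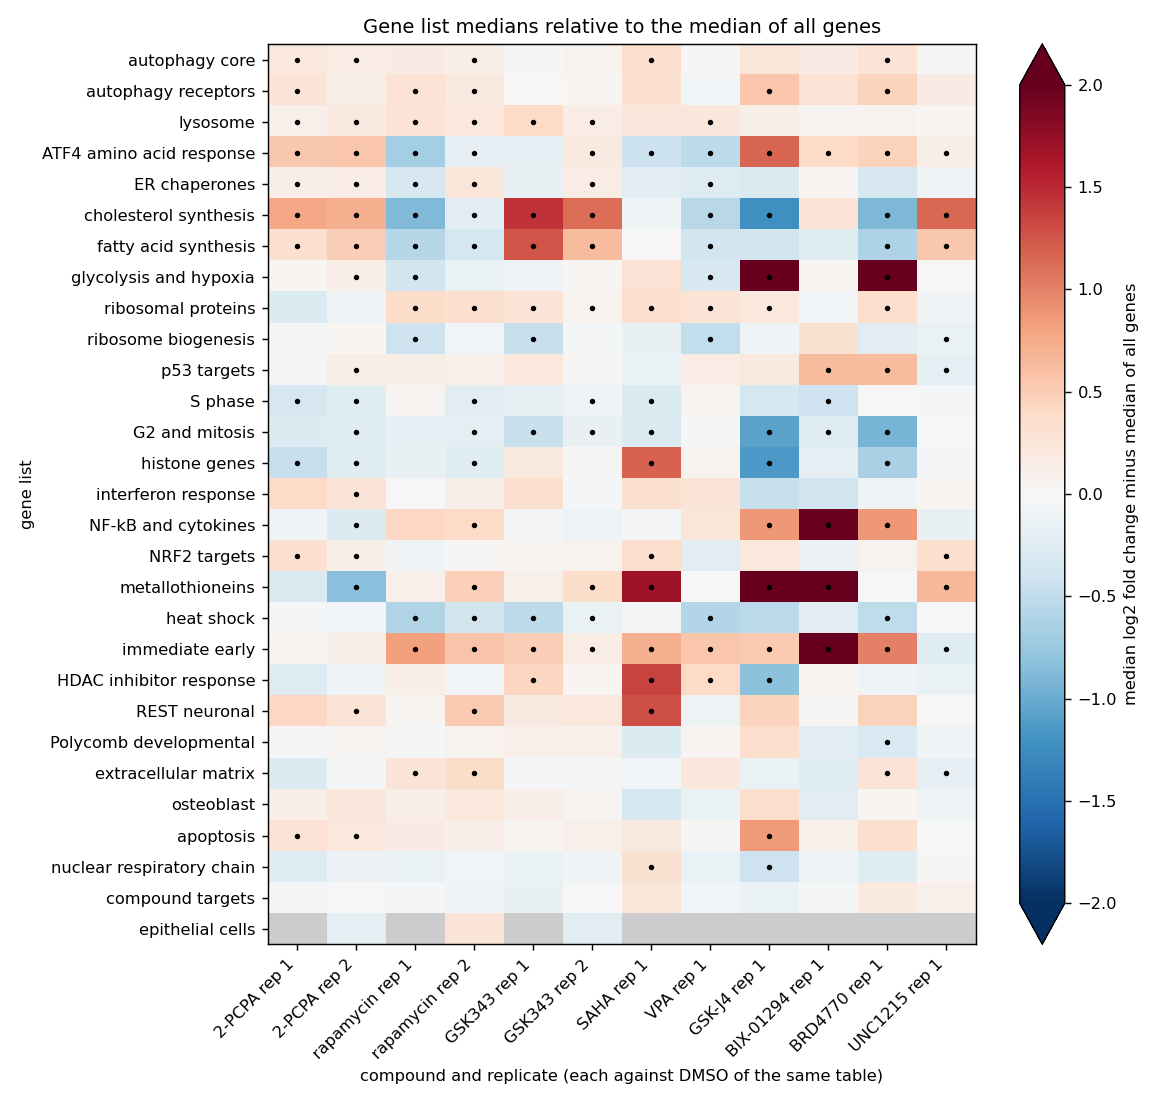
Median log2 fold change of the genes of each list minus the median of all genes (color, limited to 2 in either direction) for each treated library against DMSO of the same table; black dots mark medians below the 1st or above the 99th percentile of 10000 random lists matched on expression, and gray marks lists with too few genes. Cholesterol synthesis was above the median of all genes in both replicates of 2-PCPA (0.77 and 0.73) and of GSK343 (1.44 and 1.12) and below it in both replicates of rapamycin (−0.89 and −0.23).

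In cells given 2-PCPA, the metallothionein MT1E, a metal-binding protein, fell from 548 to 82.1 FPKM in replicate 1 and from 747 to 175 FPKM in replicate 2, a log2 fold change of −2.41 ± 0.25 (SE, n = 2 per group, limma adjusted p = 0.0294), or −2.21 after centring each library on its median. The amino acid stress genes driven by the transcription factor ATF4 lay at a median 0.52 log2 above that of all genes and cholesterol synthesis genes 0.76 above, and both lists passed camera while 0 of their 29 and 24 members passed over all genes (adjusted p = 0.490 and 0.580 with an estimated correlation). Against DMSO itself, 17 of the ATF4 and 20 of the cholesterol genes were higher in both replicates. S phase genes lay at −0.31 from all genes, with 24 of 24 lower than DMSO in both replicates (adjusted p = 0.715 with an estimated correlation). The autophagy core list lay 0.20 above all genes (adjusted p = 0.790 with an estimated correlation), but its median against DMSO was −0.01, with 7 of 33 members higher and 7 lower than DMSO in both replicates.

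Among the 29 ATF4 list genes, 0 passed over all genes tested and 6 passed when adjusted over the list alone. DDIT4, an inhibitor of mTOR complex signalling, went from 18.1 to 61.1 and from 17.7 to 77.7 FPKM (log2 fold change 1.88 ± 0.28, adjusted p = 0.271). CHAC1, which degrades glutathione, went from 7.68 to 29.2 and from 10.1 to 34.5 FPKM (1.74 ± 0.25, adjusted p = 0.271). The stress transcription factor DDIT3 (1.41) and the pseudokinase TRIB3 (1.22) were higher in both replicates without passing. The list was called by limma's camera (adjusted p = 1.85e-20), and with an estimated correlation its adjusted p = 0.490. NRF2 targets, the oxidative stress genes, lay 0.19 above all genes (camera adjusted p = 2.15e-05; adjusted p = 0.490 with an estimated correlation), with 0 of 18 passing over all genes and 3 adjusted over the list alone. Their leading member HMOX1, heme oxygenase, went from 15.0 to 136 and from 20.4 to 107 FPKM (log2 fold change 2.71 ± 0.41, adjusted p = 0.271). AKR1C3 (1.23), the cystine transporter gene SLC7A11 (0.99) and GCLM of glutathione synthesis (0.56) followed.

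For cholesterol synthesis, 0 of 24 genes passed over all genes and 0 adjusted over the list alone, with log2 fold changes of 0.95 for DHCR7, 0.94 for INSIG1, 0.79 for MSMO1 and 0.73 for SQLE. Fatty acid synthesis lay 0.33 above all genes, and its desaturase SCD had a log2 fold change of 0.86 ± 0.42. The camera adjusted p was 6.37e-19 for cholesterol and 0.000723 for fatty acid synthesis, and the adjusted p with an estimated correlation was 0.580 and 0.715. Genes past neither threshold included the autophagy genes WIPI1, which binds phosphoinositides on forming autophagosomes (4.10 to 8.60 and 7.65 to 12.6 FPKM; log2 fold change 0.78 ± 0.27), the receptor SQSTM1 (50.2 to 78.2 and 98.7 to 171 FPKM; 0.71 ± 0.26), GABARAPL1 (0.36), ULK1 (0.27), EPG5 (0.26) and MAP1LC3B (0.19). BECN1 had a log2 fold change of −0.37 (−0.17 centred) and ATG5 of −0.13 (0.07 centred). The camera adjusted p was 0.0119 for the autophagy core and 0.00465 for lysosome genes, which lay 0.16 above all genes with NPC1 (0.52) and TFEB (0.47) highest, and the adjusted p with an estimated correlation was 0.790 and 0.806. Among autophagy core, lysosome, cholesterol and fatty acid genes no member passed adjusted over the list alone. Autophagy receptors lay 0.22 above all genes and did not pass (adjusted p = 0.0663).

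On the lower side, CCNE2 (−0.88), RRM2 (−0.85) and TYMS (−0.76) led the S phase list, and KIF23 (−0.61), UBE2C (−0.59), BUB1B (−0.59) and CDC20 (−0.56) the mitotic list. Histone genes lay −0.34 from all genes, with HIST1H4H at −1.18 ± 0.26. Metallothioneins lay −0.71 from all genes, with MT1X (−1.91) and MT2A (−0.91) after MT1E. Histone and metallothionein genes have near-identical copies, so reads could be split between them. Of these lists 1 metallothionein passed over all genes, and 3 metallothioneins and 1 histone gene passed adjusted over the list alone. The camera adjusted p ranged from 2.61e-06 (S phase) to 0.00145 (metallothioneins) and lay from 0.490 to 0.731 as adjusted p with an estimated correlation. Further genes lower in both replicates without passing were the muscle-type actin binder CNN1 (−2.12), FAM65B (−1.57), the endothelin gene EDN2 (−1.69), ACTG1, a cytoplasmic actin (−1.69), and HIST1H4C (−1.68), and further genes higher were ESM1 (1.81), SCG5 (1.52), GLRX, a glutaredoxin (1.22), and the antisense row ENO1-AS1 (1.13), which is uncertain without strand. The noncoding BCYRN1 was lower (−1.60). KDM1A, the demethylase that 2-PCPA inhibits, was at 47.2 and 33.8 FPKM in replicate 1 and 50.4 and 52.1 FPKM in replicate 2 for DMSO and 2-PCPA (log2 fold change −0.21 ± 0.23, adjusted p = 0.707, or −0.01 after centring on the median). CDKN1A (−0.32; −0.12 centred), EZH2 (−0.42; −0.22 centred), MTOR (−0.28; −0.08 centred), ATG7 (−0.00) and ATG12 (−0.07) did not pass either.

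In all, limma called 3 of 12603 genes, 1 higher and 2 lower. Besides MT1E these were the small RNA rows RNU4ATAC, listed at 0 in both DMSO libraries, and SNORA26, listed at 0 in both 2-PCPA libraries. An unchanged comparison in the self-test gave 1.6 calls per simulation, not far below this count of 3. At an unadjusted p below 0.05 there were 943 genes, where chance gives 630, and 755 of them were lower, the direction of the shift of 2-PCPA replicate 1, and 188 higher. With small RNA and clone rows left out, a choice made after seeing the data, 38 genes were called (13 higher, 25 lower), among them HMOX1, DDIT4, CHAC1, DDIT3 and TRIB3 on the higher side and MT1E, MT1X and CNN1 on the lower side. Camera called 15 of 29 lists, 9 higher and 6 lower. The other called lists were apoptosis (0.27 relative to all genes; HRK 0.83, BCL2L11 0.54), interferon response (0.23; IRF9 0.81) and glycolysis and hypoxia (0.14; VEGFA 0.80, NDRG1 0.76) on the higher side, and ribosomal proteins (−0.19; RPL9 −0.54) and the nuclear respiratory chain (−0.21; NDUFB3 −0.74) on the lower side. Among random lists matched on expression the latter 2 were not low, at percentiles of 22.7 and 93.0 in replicates 1 and 2 for ribosomal proteins and of 11.5 and 10.4 for the respiratory chain. Their adjusted p with an estimated correlation lay from 0.490 to 0.820. Across all comparisons 0 list calls held with the estimated correlation. The ribosomal protein call turned direction under quantile normalization (0.02, adjusted p = 0.369) and ended without 2-PCPA replicate 1 (−0.03, adjusted p = 0.353). The balance of the called genes turned with the library left out. Leaving out 2-PCPA replicate 1 gave 47 called genes (32 higher, 15 lower) and leaving out replicate 2 gave 1026 (38 higher, 988 lower). Leaving out DMSO replicate 1 gave 44 (8 higher, 36 lower) and DMSO replicate 2 gave 7 (1 higher, 6 lower). Without 2-PCPA replicate 2 the autophagy core (limma camera adjusted p = 0.0794), lysosome (median 0.09, 0.568), fatty acid (0.0674), glycolysis (median 0.06, 0.112) and metallothionein (0.155) lists did not pass. Without 2-PCPA replicate 1 interferon response (0.204) and glycolysis (0.0569) did not, nor did glycolysis without DMSO replicate 2 (median −0.00, 0.422), and the respiratory chain did not pass with quantile normalization (median −0.09, 0.106). MT1E did not pass without DMSO replicate 1 (adjusted p = 0.272), without DMSO replicate 2 (0.227), with no replicate block (0.903), with a pseudocount of 0.1 (0.0855) or 5 (0.0522) or with no filter on low values (0.332).

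**Figure D2:**
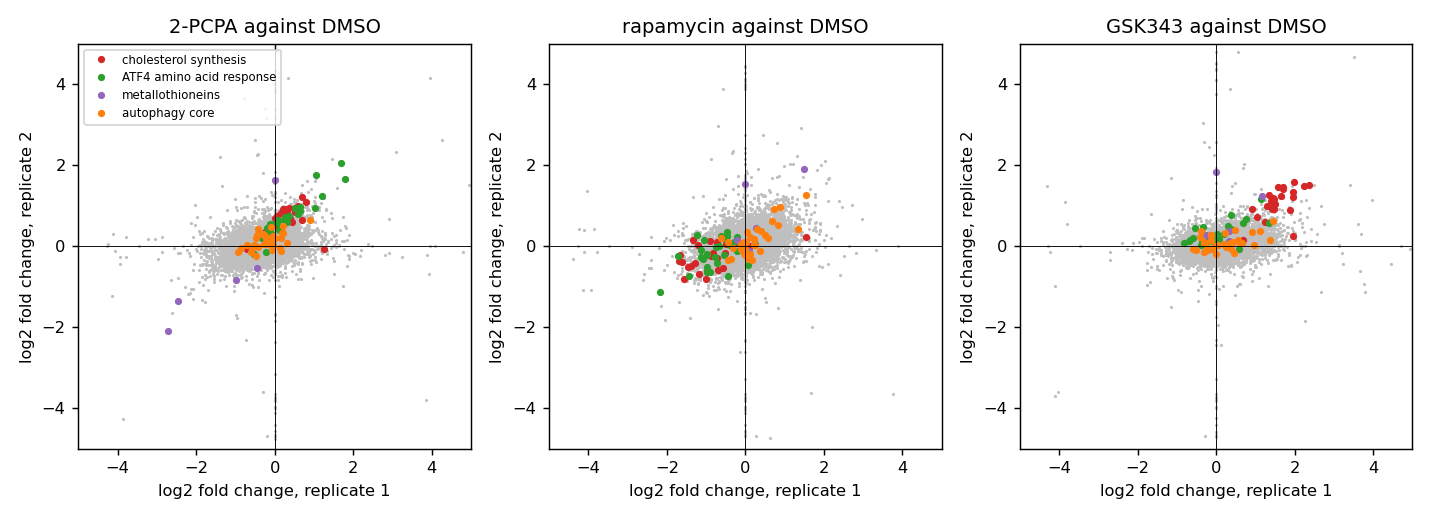
Log2 fold change against DMSO in replicate 1 (horizontal axis) and replicate 2 (vertical axis) for each tested gene (gray) and for the members of 4 lists (colored), with 295 points outside the axis range of 5. Across genes, which are not independent replicates, the replicate fold changes had a Pearson correlation of 0.11 for 2-PCPA, 0.16 for rapamycin and 0.10 for GSK343, while cholesterol genes lay to the upper right for GSK343.

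With rapamycin the ribosomal protein list was higher, by a median of 0.33 relative to all genes, with 73 of 76 members higher than DMSO in both replicates and RPS18 listed at 0 in replicate 1 (limma camera adjusted p = 1.48e-11; adjusted p = 0.848 with an estimated correlation). Relative to all genes, immediate early genes, which respond first to growth signals, were 0.63 higher, the autophagy receptors 0.27 higher and the autophagy core 0.11 higher, while ATF4 targets were at −0.42 and cholesterol synthesis genes at −0.54. Each of these lists passed camera, with 0 members past the threshold over all genes and an adjusted p = 0.848 with an estimated correlation. The medians of the ATF4 and cholesterol lists lay further from that of all genes in replicate 1 than in replicate 2. LOC645638 was the only gene besides a small RNA row past the threshold and fell from 22.4 to 4.63 FPKM and from 27.9 to 7.18 FPKM (log2 fold change −1.94 ± 0.20, n = 2 per group, limma adjusted p = 0.0492).

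The ribosomal protein genes with the largest changes were RPL28 (0.74), RPL3 (0.68), RPL13 (0.66) and RPL13A (0.60), with 0 of 76 passing over all genes or adjusted over the list alone. In the autophagy core, WDR45, a phosphoinositide-binding autophagy protein, went from 15.3 to 46.4 and from 19.3 to 48.0 FPKM (log2 fold change 1.41 ± 0.27, adjusted p = 0.386). GABARAPL1, which is conjugated to autophagosome membranes, went from 25.7 to 48.2 and from 28.1 to 55.7 FPKM (0.92 ± 0.26), followed by ULK1 (0.88), WIPI1 (0.82) and MAP1LC3B (0.39). BECN1 had 0.36 and ATG5 −0.38. Of 33 members 0 passed over all genes and 1 adjusted over the list alone (camera adjusted p = 0.00448; adjusted p = 0.848 with an estimated correlation). Among the receptors, CCPG1, which acts in turnover of endoplasmic reticulum, had a log2 fold change of 1.04 ± 0.19, NBR1 of 0.97, SQSTM1 of 0.70 and BNIP3L of 0.48, with 0 of 14 past the threshold over all genes and 2 adjusted over the list alone. Lysosome genes lay 0.27 above all genes (CLCN7 0.96, CTSF 0.87, NPC2 0.76, CTSD 0.65), with 0 of 34 passing over all genes or adjusted over the list alone. The camera adjusted p was 0.00474 for receptors and 0.00113 for lysosome, and both had an adjusted p = 0.848 with an estimated correlation.

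DDIT4 led the ATF4 list downward, from 18.1 to 3.25 and from 17.7 to 7.53 FPKM (log2 fold change −1.65 ± 0.28, adjusted p = 0.245), with CHAC1 (−1.09), PSAT1 (−0.98) and PSPH of serine synthesis (−0.80) next, and 0 of 29 passed over all genes and 4 adjusted over the list alone. HMGCS1 (−1.19), DHCR7 (−1.03) and SQLE (−0.98) led cholesterol synthesis, and SCD (−1.23) fatty acid synthesis, where no gene passed over all genes or adjusted over the list alone. The immediate early genes KLF2 (1.27), EGR1 (1.19), JUNB (1.06) and MYC (1.05) were higher, with 0 of 12 past the threshold over all genes and 3 adjusted over the list alone. Extracellular matrix genes lay 0.29 above all genes, led by CTGF (1.77), TGFBI (1.16) and CYR61 (1.05), with 0 of 18 over all genes and 2 adjusted over the list alone. Heat shock genes lay at −0.38, with CRYAB at −0.81 and HSPH1 at −0.60 and no member past a threshold. The camera adjusted p for these lists lay between 1.85e-08 and 0.00351, and each had an adjusted p = 0.848 with an estimated correlation. The remaining called lists were NF-kB and cytokines (0.35; RELB 1.14) and metallothioneins (0.41; MT2A 1.70) on the higher side, and G2 and mitosis (−0.16), ribosome biogenesis (−0.21; GNL3 −0.66) and glycolysis and hypoxia (−0.19; LDHA −0.77) on the lower side, again with an adjusted p = 0.848 with an estimated correlation.

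Further genes higher in both replicates without passing were the secreted proteoglycan gene ESM1 (3.76 ± 0.52, adjusted p = 0.143), TXNIP, an inhibitor of glucose uptake and thioredoxin (2.07 ± 0.26), SMIM14 (1.96), LOC152225 (1.86), UBALD2 (1.92), ABTB1 (1.89) and the transcription factor MAFF (1.82), and lower were HIST1H2AH (−1.82), PDLIM1 (−1.59), the hormone FGF21 (−1.54), CRABP2 (−1.14), CGN (−1.15) and TMEM255A (−1.06). MTOR was at 0.08 ± 0.26 and KDM1A at −0.44 ± 0.23. EZH2 (−0.18), ATG7 (0.04), ATG12 (−0.11), TFEB (−0.15) and CDKN1A (−0.14) did not pass. Limma called 2 of 12603 genes, both lower, LOC645638 and SNORA26, and 814 genes had an unadjusted p below 0.05 where chance gives 630. With small RNA and clone rows left out 66 genes were called (48 higher, 18 lower), including ESM1, TXNIP, MT2A, WDR45, CCPG1, CTGF and EGR1 on the higher side and DDIT4, FGF21, HMGCS1 and CHAC1 on the lower side. Camera called 15 of 29 lists, 8 higher and 7 lower. Leaving out rapamycin replicate 1 gave 38 genes (25 higher, 13 lower), replicate 2 gave 13 (7 higher, 6 lower), DMSO replicate 1 gave 42 (7 higher, 35 lower), DMSO replicate 2 gave 8 (1 higher, 7 lower) and 2-PCPA replicate 1, which enters only the shared spread, gave 0. LOC645638 passed in none of these fits (adjusted p = 0.162, 0.0950, 0.179, 0.212 and 0.365 in that order), and it also ended with only the 2 groups in the fit (0.424), no filter on low values (0.156), no replicate block (adjusted p of 1), a pseudocount of 0.1 (0.1002) or 5 (0.0782), no intensity trend (0.0955), median centring (0.0518) and quantile normalization (0.0820). Without rapamycin replicate 1 the cholesterol (median −0.12, adjusted p = 0.0547), fatty acid (0.106), ribosome biogenesis (0.465), NF-kB (0.0697) and glycolysis (0.144) lists did not pass. Without DMSO replicate 1 ribosome biogenesis (median −0.06, 0.688), NF-kB (0.0549) and glycolysis (median −0.09, 0.234) did not, and glycolysis also ended without 2-PCPA replicate 1 (0.0648) and with TPM scaling (0.0605). The calls also ended without rapamycin replicate 2 for G2 and mitosis (0.161), without DMSO replicate 2 for metallothioneins (median 0.06, 0.124) and extracellular matrix (0.0854), and with no replicate block for metallothioneins (0.112).

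**Figure D3:**
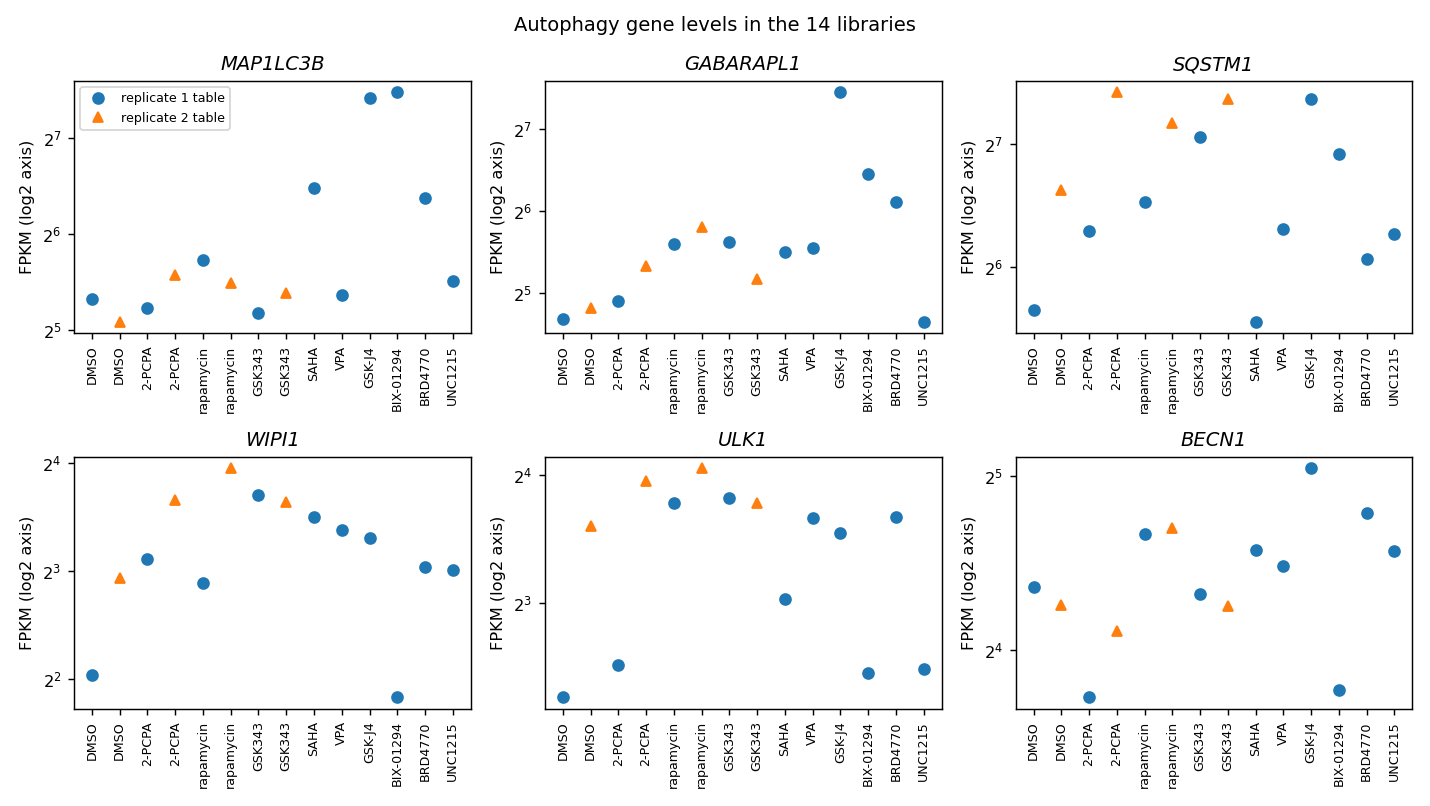
FPKM (log2 axis) of 6 autophagy genes in the 14 libraries, with circles for the replicate 1 table and triangles for the replicate 2 table; each point is 1 library and is to be compared with DMSO of the same table. GABARAPL1 ranged from 25.1 FPKM (UNC1215) to 175 FPKM (GSK-J4) in the replicate 1 table, with DMSO at 25.7 FPKM.

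With GSK343, sterol and lipid synthesis genes were higher as lists, while 0 of their members passed over all genes and both lists had an adjusted p = 0.899 with an estimated correlation. The median of the 24 cholesterol synthesis genes lay 1.28 log2 above that of all genes, and 24 of 24 were higher than DMSO in both replicates. INSIG1, a sterol-regulated inhibitor of SREBP processing, went from 8.48 to 36.3 and from 9.55 to 30.7 FPKM (log2 fold change 1.78 ± 0.29, n = 2 per group). Relative to all genes, fatty acid synthesis was 0.89 higher and G2 and mitosis genes lay at −0.30.

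No cholesterol gene passed over all genes tested, and 23 of 24 passed when adjusted over the list alone. MVD had a log2 fold change of 1.94, DHCR7 of 1.87, FDFT1 of 1.65, MSMO1 of 1.55 and HMGCS1 of 1.52, with limma adjusted p = 0.511 for INSIG1 over all genes. For fatty acid synthesis 0 of 10 passed over all genes and 8 adjusted over the list alone, with FASN (1.72), SCD (1.71), FADS2 (1.63) and ACSS2 (1.30) highest. Camera gave adjusted p = 1.42e-34 for cholesterol and 2.00e-09 for fatty acid synthesis, and both had an adjusted p = 0.899 with an estimated correlation. Lysosome genes lay 0.30 above all genes, led by CLCN7 (1.02), NPC2 (0.74) and CTSD (0.70), and ribosomal proteins 0.17 above, with no member of either passing over all genes or adjusted over the list alone (camera adjusted p = 6.53e-05 and 0.000433; adjusted p = 0.899 and 0.952 with an estimated correlation). Immediate early genes (0.14; EGR1 1.45, JUNB 0.96), metallothioneins (0.31; MT2A 1.21) and the deacetylase inhibitor response (0.23; TXNIP 1.29) were called higher, and ribosome biogenesis (−0.21) and heat shock (−0.19; HSPD1 −0.48) lower, each with an adjusted p = 0.899 with an estimated correlation; of these, 3, 1 and 1 genes of the higher lists passed adjusted over the list alone and 0 over all genes. For ribosome biogenesis NOP56 (−0.91), NOP16 (−0.48) and DKC1 (−0.42) were lowest. CENPE (−0.49), CCNA2 (−0.40) and CCNB2 (−0.39) led the mitotic genes (camera adjusted p = 8.48e-07; adjusted p = 0.899 with an estimated correlation), of which 0 passed over all genes or adjusted over the list alone.

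EZH2, which GSK343 inhibits, was at 11.8 and 8.04 FPKM in replicate 1 and 14.8 and 12.8 FPKM in replicate 2 for DMSO and GSK343 (log2 fold change −0.35 ± 0.23, adjusted p = 0.949). Genes of Polycomb-regulated developmental loci, which EZH2 represses, did not pass as a list (0.16 relative to all genes, camera adjusted p = 0.213). The autophagy core list (0.04, adjusted p = 0.207) and the receptors (0.01, adjusted p = 0.506) did not pass, while SQSTM1 (1.06 ± 0.26), WIPI1 (1.05 ± 0.27), ULK1 (0.77) and GABARAPL1 (0.63) had the highest values of the autophagy genes named in advance, and MAP1LC3B (0.07), BECN1 (−0.02), ATG5 (−0.32), ATG7 (−0.01) and ATG12 (−0.09) lay lower. TFEB (0.26), CDKN1A (0.42), MTOR (0.15) and KDM1A (0.01) did not pass. SCG5 (2.01) was higher, and HIST1H4C (−1.33), CCDC147 (−1.36), CNN1 (−1.02), NPPB (−0.95), BCYRN1 (−1.29), LOC100288842 (−0.95), HIST2H2AC (−1.01) and FAM65B (−0.92) were lower, in both replicates without passing. Limma called 2 genes, the small RNA rows MIR499A, listed at 0 in DMSO, and SNORA26, listed at 0 in GSK343, and 532 genes had an unadjusted p below 0.05 where chance gives 630. With small RNA and clone rows left out 45 genes were called (43 higher, 2 lower), of which 15 were cholesterol and 4 fatty acid synthesis genes. Camera called 10 of 29 lists, 7 higher and 3 lower. Leaving out GSK343 replicate 1 gave 40 genes (27 higher, 13 lower) and 6 lists, replicate 2 gave 84 genes (73 higher, 11 lower), DMSO replicate 1 gave 44 (9 higher, 35 lower), DMSO replicate 2 gave 7 (0 higher, 7 lower) and 2-PCPA replicate 1 gave 0. Ribosomal proteins (median 0.04, adjusted p = 0.574), immediate early (median 0.02, 0.108) and ribosome biogenesis (median −0.08, 0.0521) did not pass without GSK343 replicate 1, and the deacetylase inhibitor response did not either (median 0.11, 0.0738). Heat shock ended without GSK343 replicate 1 (0.0911), GSK343 replicate 2 (median −0.44, 0.106) and DMSO replicate 1 (0.0882), and metallothioneins without GSK343 replicate 2 (0.258), without DMSO replicate 2 (median 0.12, 0.235) and with no replicate block (0.207). Without DMSO replicate 1 ribosome biogenesis (median −0.09, 0.298) and the deacetylase inhibitor response (median 0.14, 0.0627) did not pass, and with quantile normalization ribosomal proteins (median 0.07, 0.118) and the deacetylase inhibitor response (0.0535) did not.

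The compounds were also set against each other without DMSO. Cells were sampled after 12 h of 2-PCPA and after 24 h of rapamycin or GSK343, so differences from 2-PCPA mix compound with time, and the time of the DMSO samples is not stated. The single DMSO library of each table cannot match both 12 h and 24 h. Some of the comparisons against DMSO, including those of single libraries, therefore mix compound with time too. Between 2-PCPA and rapamycin, DDIT4 was 3.54 ± 0.28 log2 higher with 2-PCPA, FGF21 2.86 ± 0.25 higher and CHAC1 2.83 ± 0.25 higher, and the metallothioneins MT1E (−2.76 ± 0.25) and MT2A (−2.61 ± 0.22) were lower, all with limma adjusted p = 0.00495 (n = 2 per group). FGF21 was listed at 0 in rapamycin replicate 1, so its fitted value rests on the pseudocount. With RNU4ATAC these made 6 called genes, 4 higher and 2 lower, against 41 higher and 9 lower with TPM scaling, 49 called without 2-PCPA replicate 1 (33 higher, 16 lower), 1265 without replicate 2 (60 higher, 1205 lower), 41 without rapamycin replicate 1 (15 higher, 26 lower) and 27 without its replicate 2 (16 higher, 11 lower). With small RNA and clone rows left out 209 genes were called, 62 higher with 2-PCPA, among them 14 of 24 cholesterol and 10 of 29 ATF4 genes, and 147 lower, and robust eBayes gave 36 higher and 48 lower. HMGCS1 (1.75), DDIT3 (1.86) and S100A4 (2.33) were higher and KLF2 (−2.48), MAP3K7CL (−1.77) and KRTAP20-4 (−2.59) lower without passing. DDIT4 (adjusted p = 0.0644) and CHAC1 (0.0866) did not pass without 2-PCPA replicate 1, MT1E did not without rapamycin replicate 1 (0.0757), and with no replicate block none of these genes passed. With no filter on low values FGF21 (0.0607), CHAC1 (0.0607), MT1E (0.0814) and MT2A (0.429) did not pass. Camera called 14 lists between 2-PCPA and rapamycin, 8 between GSK343 and rapamycin and 13 between 2-PCPA and GSK343, and 0 with an estimated correlation.

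Between GSK343 and rapamycin 10 genes were called, all higher with GSK343, and 6 of them were cholesterol synthesis genes or their regulators. HMGCS1 differed by 2.70 ± 0.28 and DDIT4 by 2.80 ± 0.28 (limma adjusted p = 0.0251). INSIG1 (2.63), MVK (2.23), FGF21 (2.04), LOC645638 (1.62) and IDI1 (1.76) and the microRNA row MIR499A were also called. ESM1 (−2.92), TGFBI (−1.60), CD44 (−1.30) and CCPG1 (−1.13) were lower without passing. The count was 98 with small RNA and clone rows left out, 16 with TPM scaling, 0 without 2-PCPA replicate 1, 118 without GSK343 replicate 2 (107 higher, 11 lower), 39 without its replicate 1 (28 higher, 11 lower) and 33 without rapamycin replicate 2 (25 higher, 8 lower). Without rapamycin replicate 1 the balance turned, with 37 genes called, 12 higher and 25 lower. HMGCS1 did not pass without GSK343 replicate 1 (adjusted p = 0.0520), rapamycin replicate 1 (0.123) or 2-PCPA replicate 1 (0.244). INSIG1 (0.0542, 0.104 and 0.378) and MVK (0.101, 0.173 and 0.244) ended in the same 3 fits, and DDIT4 ended without rapamycin replicate 1 (0.0640), without 2-PCPA replicate 1 (0.332) and with quantile normalization (0.0552). INSIG1 also ended with quantile normalization (0.0562) and median centring (0.0551), and FGF21 without GSK343 replicate 1 (0.105), rapamycin replicate 1 (0.141) or 2-PCPA replicate 1 (0.244). FGF21 moved to 4.03 (0.0691) with a pseudocount of 0.1 and to 0.80 (0.206) with 5. With no replicate block, no filter on low values or only the 2 groups in the fit, none of these 5 genes passed. Between 2-PCPA and GSK343, MT1E (−2.75 ± 0.25, adjusted p = 0.0124) and MT2A (−2.12 ± 0.22, adjusted p = 0.0278) were lower with 2-PCPA, and RNU4ATAC and MIR499A differed, which made 4 called genes. MT2A did not pass with a pseudocount of 0.1 (adjusted p = 0.0753), quantile normalization (−1.48, 0.129), TPM scaling (0.0858) or without GSK343 replicate 1 (0.102). Both MT2A and MT1E ended with no filter on low values (0.545 and 0.139), with no replicate block (0.819 for both) and with only the 2 groups in the fit (0.897 for both). MT1X (−2.14), PINK1 (−1.46) and RAMP2 (−1.42) were lower and HMOX1 (1.24), CHAC1 (1.02), ITGA2 (0.85) and LOC100288842 (0.73) higher without passing. The count was 19 with small RNA and clone rows left out, 50 without 2-PCPA replicate 1 (32 higher, 18 lower with 2-PCPA) and 2485 without its replicate 2 (45 higher, 2440 lower), so the balance turned. It was 39 without GSK343 replicate 1 (12 higher, 27 lower) and 167 without its replicate 2 (8 higher, 159 lower).

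The fold changes of 2-PCPA and rapamycin against the same DMSO libraries had a correlation of 0.39 across 12603 genes. Simulated noise for unchanged groups and a control shared within each table gave 0.50. Sharing a control sets that value, and differing effects lower a correlation. The lower 0.39 therefore does not show that the compounds were less alike than unchanged groups. The covariance of the 2-PCPA and rapamycin fold changes was 0.0796 against a simulated 0.0559. After removing the shared-control term 0.0241 remained, with an SD of 0.0435 between tables. With 2-PCPA and rapamycin taken from different tables, which share no library, the correlations were 0.04 and −0.01. The 2 replicates of the same compound, also from different tables, correlated only at 0.11 for 2-PCPA and 0.16 for rapamycin. Low values across tables therefore do not show that a shared effect was absent. Genes called lower in both comparisons numbered 1 and genes called higher in both 0. The shared gene, the small RNA row SNORA26, was listed at 0 in all treated libraries of the replicated compounds and was called for GSK343 too. This overlap cannot be told apart from high values in the shared DMSO libraries. The 0.000317 genes that independent lists would share are therefore no expectation for it. With 1 DMSO library per table the controls could not be split, and part of any excess may come from the shared controls.

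The 6 other compounds had 1 library each, so their values have no replicate check and no test was made. Of 12804 genes in the replicate 1 table, the number at least 2-fold from DMSO was 2049 for BIX-01294 (1276 higher, 773 lower), 1905 for GSK-J4 (1142 and 763), 1488 for SAHA (997 and 491), 1381 for BRD4770 (761 and 620), 563 for VPA (360 and 203) and 391 for UNC1215 (230 and 161). Small RNA or clone rows were 180, 204, 175, 155, 150 and 121 of these in the same order, so they weigh most in the counts of VPA and UNC1215. TPM scaling changed the split to 954 higher and 1049 lower for BIX-01294, 963 and 955 for GSK-J4 and 698 and 780 for SAHA. As a guide to what 1 library shows, 2-PCPA replicate 1 had 1211 such genes (162 and 1049, or 425 and 263 after centring on its median), GSK343 797 and rapamycin 676. Of those measured in replicate 2, 3.16%, 6.98% and 10.5% moved 2-fold the same way again, without centring. For 2-PCPA 922 of the 1014 genes so measured were lower in replicate 1, the direction of the shift of that library. For scale, 243, 208 and 303 of the 12603 tested genes were 2-fold from DMSO in replicate 2, in either direction.

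**Figure D4:**
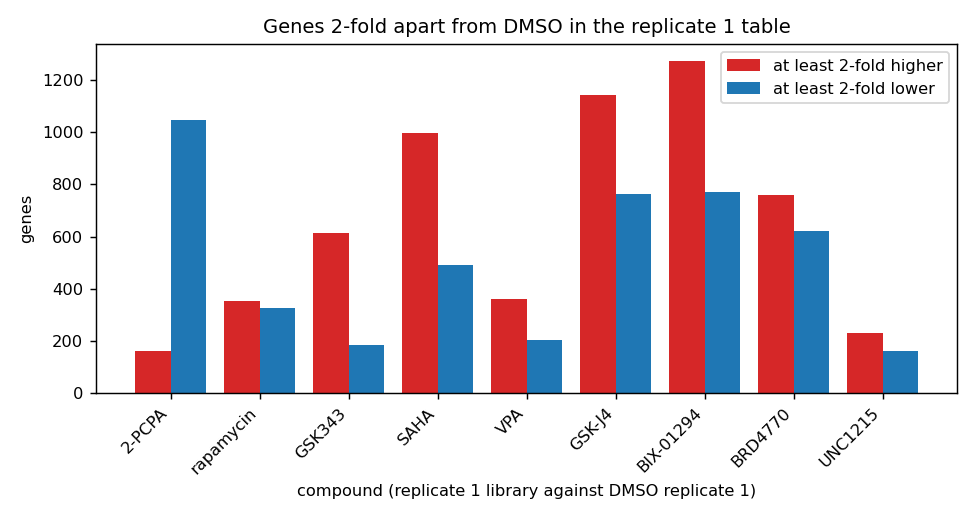
Number of genes at least 2-fold higher (red) or lower (blue) than DMSO replicate 1 in each treated library of the replicate 1 table, out of 12804 genes, small RNA and clone rows included. The bars range from 161 genes lower with UNC1215 to 1276 genes higher with BIX-01294.

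GSK-J4 had its metallothionein list 4.62 log2 above all genes (6 of 6 genes at least 2-fold higher), with MT1X at 78.9 and 3700 FPKM in DMSO and GSK-J4, and its glycolysis and hypoxia list 2.73 above (22 of 22 genes at least 2-fold higher), with the carbonic anhydrase CA9 at 0.609 and 25.9 FPKM, HK2 at 4.65 and 93.5 FPKM and NDRG1 at 30.1 and 857 FPKM. Both medians lay above the 99th percentile of 10000 matched random lists. HMOX1 went from 15.0 to 914 FPKM, DDIT4 from 18.1 to 639 FPKM and the natriuretic peptide gene NPPB from 5.98 to 335 FPKM. ATF4 targets were 1.16 above and the mitophagy receptors BNIP3 (19.0 to 248 FPKM) and BNIP3L (37.1 to 241 FPKM) led the autophagy receptors (0.55 above). MAP1LC3B went from 40.0 to 170 FPKM, GABARAPL1 from 25.7 to 175 FPKM and SQSTM1 from 50.2 to 165 FPKM. Cholesterol (−1.23), histone (−1.15) and mitotic genes (−1.06) lay below the 1st percentile, with ACAT2 at a log2 fold change of −2.44 and CDC20 at −1.65. Also among the 6 highest and 6 lowest genes were MT1G (listed at 0 in DMSO, 362 FPKM), MT1B (listed at 0 in DMSO, 167 FPKM), HIST1H2BJ (34.1 FPKM in DMSO, listed at 0), BCMS (8.78 FPKM in DMSO, listed at 0), ENHO (−3.14), ZSCAN31 (−3.14), MTND5 (−2.98) and LOC100129858 (6.90 FPKM in DMSO, listed at 0). The GSK-J4 targets KDM6A and KDM6B went from 2.58 to 3.31 and from 3.42 to 12.1 FPKM. The 14 genes named in advance ranged from −0.60 (TFEB) to 2.72 (GABARAPL1).

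BRD4770 also had glycolysis and hypoxia genes far above all genes (2.06, 19 of 22 at least 2-fold higher), with CA9 at 36.1 FPKM, ALDOC at a log2 fold change of 4.16 and HK2 at 57.4 FPKM, and BNIP3 at 226 FPKM. ESM1 went from 0.431 to 42.4 FPKM and TXNIP from 0.788 to 44.4 FPKM. The autophagy core (0.28) and receptors (0.44), immediate early genes (1.01) and p53 targets (0.63; GDF15 log2 fold change 2.23) lay above the 99th percentile. Mitotic (−0.93; PLK1 −2.33), cholesterol (−0.89) and histone genes (−0.64) lay below the 1st, and CRYAB (−4.02) and TNNT2 (−3.87) were among the lowest single genes. The extremes further included BCL2A1 (listed at 0 in DMSO, 16.5 FPKM), SRRM3 (−3.33), MLLT10P1 (8.80 FPKM in DMSO, listed at 0) and MATN2 (−3.15). The range over the genes named in advance was −1.33 (TFEB) to 1.40 (GABARAPL1). BIX-01294, directed at the same enzymes but given at another dose and for another time, had metallothioneins 3.18 above all genes, immediate early genes 2.66 above (13 of 13 at least 2-fold higher; EGR1 from 6.49 to 263 FPKM, FOS from 0.882 to 44.1 FPKM), NF-kB and cytokine genes 1.98 above and p53 targets 0.63 above (GADD45A from 56.4 to 806 FPKM). Its ATF4 list was 0.41 above, with DDIT3 from 9.56 to 354 FPKM and ATF3 from 8.76 to 114 FPKM, and S phase genes were −0.41 from all genes. MAP1LC3B went from 40.0 to 178 FPKM and CDKN1A from 57.9 to 244 FPKM. The largest differences of BIX-01294 also covered GEM (5.15), DUSP2 (5.10), DUSP5 (4.93), MT1G (listed at 0 in DMSO, 25.1 FPKM), BCMS (8.78 FPKM in DMSO, listed at 0), TPGS1 (−2.90), LOC100131138 (6.34 FPKM in DMSO, listed at 0), TOPORS-AS1 (5.87 FPKM in DMSO, listed at 0), BMP4 (−2.77) and RPL23AP64 (5.61 FPKM in DMSO, listed at 0). The range over the genes named in advance was −0.56 (BECN1) to 2.12 (MAP1LC3B). EHMT1 was at 7.64 FPKM in DMSO, 8.11 FPKM with BIX-01294 and 7.79 FPKM with BRD4770. EHMT2 was listed at 0 in all libraries of the replicate 1 table, which may be a failed estimate. In the replicate 2 table it was at 31.9 FPKM in DMSO and from 24.8 (rapamycin) to 33.8 FPKM (GSK343) in treated libraries. BIX-01294 and BRD4770 had 2691 genes 2-fold apart from each other.

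SAHA had its deacetylase inhibitor response list 1.35 above all genes, neuronal genes repressed by REST 1.30 above, histone genes 1.19 above and metallothioneins 1.70 above. The synaptic vesicle gene SYP went from 0.513 to 26.7 FPKM, HIST1H1C from 217 to 882 FPKM, CLU from 662 to 2244 FPKM and MT1X to 542 FPKM. The autophagy core was 0.33 above the median of all genes, with MAP1LC3B at 89.0 FPKM against 40.0 FPKM and WIPI1 at 11.3 FPKM against 4.10 FPKM. ATF4 targets lay −0.43 from all genes (MTHFD2 −1.53), and TNNT2 (−4.33) and the collagen chaperone SERPINH1 (−3.12) were among the lowest genes. Other genes at the extremes with SAHA were HIST1H2BC (3.69), REEP6 (3.60), PPM1J (3.56), SNAR-F (listed at 0 in DMSO, 10.5 FPKM), BCMS (8.78 FPKM in DMSO, listed at 0), MGC20647 (listed at 0 with SAHA), CXCR7 (−3.06) and TRIM22 (−3.03). HDAC1 was at 98.8 FPKM against 80.1 FPKM, HDAC2 at 32.7 against 26.1 FPKM and HDAC3 at 41.5 against 29.5 FPKM. The range over the genes named in advance was −0.28 (EZH2) to 1.27 (WIPI1). VPA, for which the label states 20 μM, a dose that was not checked here, and the same time, had its deacetylase inhibitor response list 0.39 above all genes and histone genes within the random range. Its other lists outside the range included heat shock (−0.58), cholesterol (−0.56), ATF4 targets (−0.53; DDIT4 18.1 to 4.50 FPKM), ribosome biogenesis (−0.49), immediate early genes (0.55) and ribosomal proteins (0.27). ULK1 (1.24) and ATG5 (−0.54) bounded its genes named in advance. With VPA the extremes, by log2 fold change, included PIGY (listed at 0 in DMSO, 12.3 FPKM), ZNF32-AS1 (listed at 0 in DMSO, 5.21 FPKM), TNFRSF13C (2.34), GPR27 (2.25), BCYRN1 (−2.59), SREK1IP1 (−2.42), ANXA2P2 (−2.16) and ENHO (−2.14). The SAHA and VPA libraries had 1447 genes 2-fold apart.

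UNC1215 had cholesterol synthesis 1.15 above all genes, with 18 of 24 genes at least 2-fold higher, among them MVD (31.7 to 96.2 FPKM), MSMO1 (50.7 to 151 FPKM) and HMGCS1 (35.8 to 103 FPKM). Fatty acid synthesis was 0.54 above (SCD 57.2 to 153 FPKM) and metallothioneins 0.67 above. L3MBTL3 was at 2.46 FPKM in DMSO and 2.09 FPKM with UNC1215. WIPI1 (0.82) and TFEB (−0.41) bounded the genes named in advance. The extremes of UNC1215, by log2 fold change, included LOC100630923 (listed at 0 in DMSO, 6.46 FPKM), RPS17L (listed at 0 in DMSO, 5.23 FPKM), TMX2-CTNND1 (2.54), C12orf39 (2.20), SRP14-AS1 (2.16), PRR4 (−2.89), BCMS (−2.78), ENHO (−2.57), BLOC1S5 (−1.99) and XAGE5 (−1.97). SNURF, which overlaps other transcripts at its locus, had 0.00460 FPKM in DMSO replicate 1 and 33.3 FPKM with UNC1215, 34.4 FPKM with SAHA, 40.2 FPKM with VPA and 50.2 FPKM with BRD4770, and its value is uncertain because the strand of the reads is not stated.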

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

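The results below stood out because a difference between 2 compounds passed by limma and the signs against DMSO were opposite in both replicates. Only the sign against DMSO was asked for, not its size, and each sign rests on the DMSO library of its table. Some of these fold changes were small, with MT1E at 0.36 for rapamycin and 0.35 for GSK343 and FGF21 at 0.50 for GSK343. Of these genes only MT1E with 2-PCPA passed against DMSO, so opposite movement was not shown by a test. Between 2-PCPA and rapamycin these were DDIT4 (log2 fold change 3.54), FGF21 (2.86), CHAC1 (2.83), MT1E (−2.76) and MT2A (−2.61). Between GSK343 and rapamycin they included DDIT4 (2.80), HMGCS1 (2.70), INSIG1 (2.63), MVK (2.23), FGF21 (2.04) and IDI1 (1.76). Between 2-PCPA and GSK343 they were MT1E (−2.75) and MT2A (−2.12). The comparison of compounds does not use the DMSO libraries for its difference, but FGF21 was listed at 0 in rapamycin replicate 1.

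Of the tests in the next paragraphs, those of olfactory receptor genes and of the chromosome 17 genes were written before their values were seen and the others after.

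The 2-PCPA replicate 1 library stood apart from its table in its median. Reads from DNA or unspliced RNA spread over silent genes fit, since 28.5% of olfactory receptor genes were above 0 against at most 6.62% in the other libraries. Fewer reads would put its depth below that of the other libraries, but its depth relative to DMSO was 0.818 and those of BIX-01294 (0.551), GSK-J4 (0.655) and UNC1215 (0.688) were lower. A shift of the median caused by 2-PCPA would recur, but the median of replicate 2 was 0.00618. FPKM values are relative to the reads of each library, so this median cannot show a uniform change of all genes. The FPKM sum of 2-PCPA replicate 1 was 291956, against 456039 (DMSO) to 531006 (SAHA) in the other libraries of its table.

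The VPA library lay close to rapamycin replicate 1, with 331 genes 2-fold apart, counted directly between them without the DMSO library. The next closest pair with VPA had 480 and the most distant pair of that table had 3459. DMSO and UNC1215 were nearly as close, with 391, and VPA and DMSO had 563. All these counts include small RNA and clone rows, which were 121 of the 391 and 150 of the 563. Whether the VPA library holds a rapamycin-treated sample cannot be told apart. The deacetylase inhibitor response of VPA against rapamycin lay at the 99.8th percentile of random lists, but 8 of 28 lists lay outside the 1st to 99th percentiles where at most 3 were to do so for the bounds to decide, a limit added after the value was seen.

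Of the genes, 167 were listed at 0 in all 10 libraries of the replicate 1 table while averaging over 20 FPKM in the other, 134 of them small RNA or clone rows. Silence in those cultures would not gather them in a region, but 69.7% of the 33 named genes among them lay between MOG and KIFC1 in the major histocompatibility region against 1.34% of all such genes. Reads placed on alternate haplotype copies of the genome cannot be told apart from other causes. Between ARHGAP27 and WNT3, another region with such copies, 10% of genes were listed at 0 (1 of 10, exact upper bound 44.5%), and gene matching there was corrected after the value was seen.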

How the results depend on the processing

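The counts of called genes rest on 2 libraries per group and on the prior spread, and the cause of these movements was not tested. Against DMSO unless another compound is named, 3 genes were called for 2-PCPA, 2 for rapamycin and 2 for GSK343, and 6, 10 and 4 between compounds. In the self-test an unchanged comparison gave 1.6 calls per simulation, so the counts against DMSO are near what the fit gives by chance. With changed genes, false calls in the self-test also exceeded what the adjustment threshold allows. Calls just past the threshold, those between compounds included, are therefore uncertain. Small RNA and clone rows and genes listed at 0 were chosen for leaving out after the data were seen. With a pseudocount of 0.1 the genes called numbered 0 for 2-PCPA, 0 for rapamycin, 0 for GSK343, 6 for GSK343 against rapamycin and 1 for 2-PCPA against GSK343, and the genes 2-fold apart 1088 for VPA, 2111 for BRD4770 and 830 for UNC1215. With a pseudocount of 5 the genes called numbered 1 for 2-PCPA, 0 for rapamycin and 1 for GSK343, and the genes 2-fold apart 527 for SAHA, 133 for VPA, 801 for GSK-J4, 771 for BIX-01294, 476 for BRD4770 and 103 for UNC1215. With no filter on low values the genes called numbered 1 for 2-PCPA, 0 for rapamycin, 0 for GSK343, 2 for 2-PCPA against rapamycin, 0 for GSK343 against rapamycin and 1 for 2-PCPA against GSK343. With a mean of at least 5 FPKM the genes called numbered 4 for rapamycin, 1 for GSK343, 32 for 2-PCPA against rapamycin, 35 for GSK343 against rapamycin and 2 for 2-PCPA against GSK343, and the genes 2-fold apart 792 for SAHA, 238 for VPA, 1154 for GSK-J4, 1229 for BIX-01294, 745 for BRD4770 and 137 for UNC1215. With median centring the genes called numbered 0 for rapamycin, 0 for GSK343 and 12 for 2-PCPA against rapamycin. With quantile normalization the genes called numbered 0 for rapamycin, 0 for GSK343, 14 for 2-PCPA against rapamycin, 6 for GSK343 against rapamycin and 2 for 2-PCPA against GSK343. With TPM scaling the genes called numbered 1 for GSK343, 50 for 2-PCPA against rapamycin and 16 for GSK343 against rapamycin. With no replicate block the genes called numbered 1 for 2-PCPA, 0 for rapamycin, 0 for GSK343, 1 for 2-PCPA against rapamycin, 0 for GSK343 against rapamycin and 1 for 2-PCPA against GSK343. Without the intensity trend the genes called numbered 1 for rapamycin. With robust eBayes the genes called numbered 16 for 2-PCPA, 26 for rapamycin, 18 for GSK343, 84 for 2-PCPA against rapamycin, 63 for GSK343 against rapamycin and 8 for 2-PCPA against GSK343. With small RNA and clone rows left out the genes called numbered 38 for 2-PCPA, 66 for rapamycin, 45 for GSK343, 209 for 2-PCPA against rapamycin, 98 for GSK343 against rapamycin and 19 for 2-PCPA against GSK343. With genes listed at 0 in 4 libraries of the replicate 1 table left out the genes called numbered 14 for 2-PCPA, 25 for rapamycin, 10 for GSK343, 73 for 2-PCPA against rapamycin, 65 for GSK343 against rapamycin and 7 for 2-PCPA against GSK343. With only the 2 groups compared in the fit the genes called numbered 272 for 2-PCPA, 0 for rapamycin, 0 for GSK343, 389 for 2-PCPA against rapamycin and 0 for GSK343 against rapamycin. Leaving out 1 library gave 7 to 1026 for 2-PCPA, 0 to 42 for rapamycin, 0 to 84 for GSK343, 27 to 1265 for 2-PCPA against rapamycin, 0 to 118 for GSK343 against rapamycin and 39 to 2485 for 2-PCPA against GSK343. For gene lists it gave 11 to 18 for 2-PCPA, 12 to 15 for rapamycin and 6 to 11 for GSK343. With an estimated correlation 0 lists were called for 2-PCPA, rapamycin and GSK343, and with fry 0 as well. The ribosomal protein median in 2-PCPA turned to 0.0218 with quantile normalization. By fry the autophagy core (0.20), lysosome (0.16) and glycolysis and hypoxia (0.14) in 2-PCPA were directed downward because fry does not set them against other genes. Without rapamycin replicate 1 the endoplasmic reticulum chaperones in rapamycin turned to 0.20, and over all libraries left out their median ranged from −0.22 to 0.20.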

Other observations

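The sterol genes were higher with some compounds and lower with others. Relative to all genes, the median of cholesterol synthesis was 1.44 with GSK343 replicate 1, 1.15 with UNC1215 and 0.77 with 2-PCPA replicate 1, and was −1.23 with GSK-J4, −0.89 with BRD4770 and rapamycin replicate 1 (−0.23 in its replicate 2) and −0.56 with VPA, with 0.27 for BIX-01294 and −0.08 for SAHA between them. The ATF4 list did not follow the same division, with 1.16 for GSK-J4, 0.54 for 2-PCPA replicate 1, −0.53 for VPA and −0.69 for rapamycin replicate 1, but −0.16 for rapamycin replicate 2, and GSK343 went from −0.19 in replicate 1 to 0.18 in replicate 2. Values of VPA may not be separate from those of rapamycin, since its library could hold a rapamycin-treated sample.

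The autophagy core had modest medians beside the lists above, with 0.33 for SAHA and 0.28 for BRD4770 at the most among libraries of the replicate 1 table above the 99th percentile. In 2-PCPA the core lay 0.20 above all genes, with a median of −0.01 against DMSO. Without 2-PCPA replicate 2 it lay 0.22 above (limma adjusted p = 0.0794), and over all libraries its adjusted p was 0.790 with an estimated correlation.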
